A study of Mus musculus with 24 samples.

How the data were processed

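The series held 24 arrays on an Agilent mouse cDNA platform with 9275 probes. Lung and skin were each measured in A/J, C57BL/6J and C3H/HeMs mice without irradiation and at 1 h, 12 h and 72 h after it, with 1 array per strain, tissue and time, and the replicate number of a sample stood for its strain. Per the labels' protocols, every array held RNA pooled from 3 female mice, extracted with a phenol reagent and a silica column and labelled directly. Lung RNA carried Cy3 and skin RNA Cy5, in each case against a common reference in the other dye. The deposited values were log10 ratios of Cy5 over Cy3, which the authors made with Agilent's Feature Extraction software per the submitters' processing notes. Its version, its background and dye steps and any filter on spots were not given in the sources used here. Deposited log10 ratios were limited to ±2, which 8 to 35 probes per lung array and 15 to 42 per skin array had reached, and no value was missing.

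The lung values were turned in sign so that every ratio read sample over reference, multiplied by 3.32 to give log2 ratios and centred on the median of each array. This direction was read from the lists of lung epithelium, skeletal muscle and epidermal differentiation genes. Before centring, the array medians lay between -0.0577 and -0.0044 and the SD between 0.287 and 0.468 on the log10 scale. Probes were named from the platform annotation of 2007, checked against a current gene table by Entrez ID, in which 0 symbols changed. A single gene symbol was given for 6433 probes, several symbols for 381 and none for 2461. Probes of the same gene were averaged, which gave 8750 features, 5908 of them with a symbol, and probes with several symbols or none were kept as single features under their identifiers.

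All tests used limma 3.58.1 in R 4.3.3. For each tissue a linear model with 4 groups and the strain as a block was fitted to 12 arrays, which left 6 residual degrees of freedom, followed by empirical Bayes moderation and Benjamini-Hochberg adjustment over all features with a threshold of 0.05. Contrasts were each time against control and 72 h against 1 h. Further fits tested the 9 irradiated arrays against the 3 controls, the strains (an F test), and the interaction of strain and irradiation. A fit of all 24 arrays with a block for each strain in each tissue, with 12 residual degrees of freedom, tested the difference and the mean of the skin and lung responses. Features changed at least 2-fold in the same direction in all 3 strains were counted from each strain's own control, with the count that independent lists would give, and overlaps between tissues were tested with Fisher's exact test.

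Gene lists were written down from general knowledge. Of 29 lists with 12 to 52 genes each, 28 had at least 5 measured members and were tested with camera at a preset inter-gene correlation of 0.01, adjusted over all lists and times of a tissue. Melanocyte genes, with 3 measured, were not tested. Members were also adjusted over the list alone, and every list test was repeated with an estimated correlation.

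The comparisons, tests, gene lists, alternatives and the rule for naming genes were fixed before the data were examined. For each tissue and time the rule takes, among features with a symbol that passed and moved in the same direction in all 3 strains, the 10 largest rises and the 10 largest falls. Where none passed, the 5 genes with the smallest p are given as values. Genes in common are the 10 with the largest smaller change of both tissues at each time, other tests give the 5 largest changes per direction or the 5 smallest p of an F test, and each list gives up to 4 members with the smallest p per comparison. Names that are only clone or prediction identifiers were passed over. Tissue markers, clock genes, 8 genes of the 2-fold counts, Hc, Alad and Xdh are named outside this rule and were chosen after their values were seen, as were values given for genes already named elsewhere. Tests of the mean of both tissues and of list differences between tissues were added after seeing the data.

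Pairing was checked from the deviations of arrays from their group means, since the replicate number is the strain. In lung the correlations within a strain ran from -0.05 to 0.59 in A/J, 0.16 to 0.71 in C57BL/6J and 0.02 to 0.52 in C3H/HeMs. In skin they ran from -0.02 to 0.68, 0.17 to 0.32 and -0.05 to 0.47. Strain stayed in every fit as a factor of the design.

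The limma fits, the list tests and the 2-fold counts were tested on simulated data of the same size, with the mean level of each feature, independent noise drawn from the fitted spread and no strain effects, and 100 of 8750 features changed per fold size. Of features changed 2-fold, 56%, 57% and 61% were recovered in lung at 1 h, 12 h and 72 h and 17%, 17% and 16% in skin. At 4-fold the shares were 92%, 94% and 95% in lung and 84%, 81% and 82% in skin. For 72 h against 1 h 59% of 2-fold and 94% of 4-fold changes were recovered in lung and 20% and 88% in skin, and for irradiated arrays against controls 75% and 99% in lung and 46% and 95% in skin. Strain differences gave 78% and 97% in lung and 38% and 88% in skin. The interaction of strain and irradiation gave 2% and 37% in lung and 0% and 0% in skin. Skin minus lung gave 9%, 8% and 13% at 2-fold and 56%, 57% and 61% at 4-fold for 1 h, 12 h and 72 h, and the mean of both tissues gave 78%, 80% and 78% and 95%, 97% and 96%. Features called without a simulated change numbered 0 to 15 per comparison, up to 12.2% of the calls against the 5% set by the threshold. The highest shares were 12.2% and 10.8% for skin minus lung at 12 h and 72 h (9 false beside 65 and 74 recovered), 9.3% for the interaction in lung (4 beside 39), 8.03% for strains in skin (11 beside 126), 7.81% for the mean at 12 h (15 beside 177) and 6.95% for irradiated lung arrays (13 beside 174). A list shifted by 0.8 was called in each tissue, and in the difference between tissues when shifted in skin alone, with 0 other lists called. The simulated noise held no correlation between genes, so this says little on how often lists are called by chance in the real arrays. Of 100 features raised 4-fold at 12 h, the 2-fold count in all 3 strains found 96 in lung with 6 false and 83 in skin with 9 false, and 80 in both tissues with 0 false.

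Alternatives were the values as deposited without centring, quantile scaling, every probe as its own feature, no strain block, only the groups compared, a fold minimum, moderation with trend and robust options, and leaving out each strain and each array. Added after seeing the data were the set of the lung arrays as a block (pairs of strains included), the 4 lung arrays left out, probes at the limit left out, probes with ratios of exactly 0 left out, and only named genes. No array was left out of the results given first. Spot intensities and image files were not used here.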

Results

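Gene expression was measured in lung and skin of female mice of the inbred strains A/J, C57BL/6J and C3H/HeMs. Mice were left without irradiation or were killed 1 h, 12 h or 72 h after local gamma irradiation, with 10 Gy to the thorax for lung and 30 Gy to the hind leg for skin. Each of the 24 arrays compared RNA pooled from 3 mice with a reference mixed from commercial RNA of 10 organs. Every tissue thus had 4 groups of 3 arrays, 1 array per strain, and p-values measure the spread between pools of different strains, not between single mice. The series asks which genes respond to radiation in lung as well as skin and in all 3 strains. A total of 8750 features were tested, and the number of arrays limits the precision of every value.

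The ratios of tissue marker genes set the direction of the values. In lung, all 9 measured lung epithelium genes lay above the reference, with a median log2 ratio of 2.45, and in skin all 15 epidermal differentiation genes lay above it, with a median of 4.63. Sftpc, which encodes surfactant protein C, had a log2 ratio of 2.45 ± 0.78 (SD, n = 12 arrays) in lung and sat at the lower limit of -6.64 in skin. Scgb1a1, the club cell secretory protein, was at 2.85 ± 0.64 in lung and -5.62 ± 0.70 in skin, while Krt10, a keratin of differentiated epidermis, was at 5.04 ± 0.95 in skin and -3.16 ± 0.97 in lung (SD, n = 12 each). Skeletal muscle genes, the other list fixed for skin, were less clear, with 6 of 18 above the reference and a median of -0.45. Between lung and skin arrays, the correlation across probes ran from -0.52 to -0.12 as deposited and from 0.12 to 0.52 once the lung ratios, labelled in the opposite dye, were turned.

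Lung arrays fell into separate sets. The 12 h and 72 h arrays of A/J and C3H/HeMs stood apart from the other 8 lung arrays on the first principal component, which held 39.9% of the variance. Correlations were 0.90 to 0.96 within the 8 arrays, 0.89 to 0.94 within the 4 and 0.80 to 0.89 between them. Ratios of exactly 0 numbered 674 and 607 probes on the A/J arrays and 183 and 115 on the C3H/HeMs arrays at 12 h and 72 h, against 1 to 23 on the other 8. All lung arrays of C57BL/6J belonged to the larger set, so its changes at 12 h and 72 h compare arrays within that set.

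In lung 1 h after thoracic irradiation, Cdkn1a, which encodes the p21 inhibitor of cyclin-dependent kinases, rose 4.71-fold (log2 2.23 ± 0.20 SE, n = 3 pools per group, limma adjusted p = 0.0133). Its change was 1.79 in A/J, 2.42 in C57BL/6J and 2.49 in C3H/HeMs. The 20 measured p53 targets rose as a list, with a median log2 change of 0.16 (adjusted p = 2.39e-06, and adjusted p = 0.764 with an estimated correlation). When adjusted over the list alone, 5 members rose, 0 fell and 15 did not pass, and only Cdkn1a passed over all features. Besides Cdkn1a these held Trp53inp1, a p53-induced nuclear protein (1.31 ± 0.19 SE), Mdm2, the ubiquitin ligase that degrades p53 (0.73 ± 0.19), and Ccng1, cyclin G1 (0.69 ± 0.20).

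Other lists also moved in lung at 1 h, by less. Immediate early genes rose (24 measured, median 0.20, adjusted p = 0.000531, and adjusted p = 0.748 with an estimated correlation), although the member that passed when adjusted over the list alone, Ccn1, a matricellular protein, fell by 0.66 on the log2 scale, and 23 did not pass. The nuclear receptor gene Nr4a2 was at 0.80 ± 0.26 SE. Extracellular matrix and fibroblast genes (median 0.12, adjusted p = 0.00232), neutrophil genes (0.11, adjusted p = 0.017) and heart muscle genes (0.15, adjusted p = 0.0297) rose, with adjusted p = 0.764 to 0.939 for these 3 with an estimated correlation. B cell genes (-0.22, adjusted p = 0.00548) and macrophage and monocyte genes (-0.12, adjusted p = 0.0065) fell, and mitosis genes fell (-0.05, adjusted p = 0.0371) with a median that turned to 0.0056 under quantile scaling. With an estimated correlation the lists that fell had adjusted p = 0.764 to 0.939. The strains differed in direction, with medians in A/J, C57BL/6J and C3H/HeMs of 0.21, 0.28 and -0.07 for matrix, -0.01, 0.59 and 0.32 for neutrophil, -0.33, 0.05 and -0.16 for macrophage and -0.17, 0.01 and -0.22 for mitosis genes. Among the 9 neutrophil genes Csf3r, the receptor of granulocyte colony-stimulating factor, rose (0.66 ± 0.18 SE), and adjusted over the list alone none of the other 8 passed, nor any of the 30 matrix, 13 heart, 16 B cell, 15 macrophage or 33 mitosis genes passed.

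At this time 1 of the 8750 features passed, and 196 had an unadjusted p under 0.05, where chance gives 438. The count was 0 with only the groups compared in the fit, without any 1 of the 3 strains, and without the A/J control, the A/J 72 h, the C57BL/6J 1 h, or the C3H/HeMs control, 1 h or 12 h array, and Cdkn1a also missed the threshold without the C57BL/6J control. Of the lists, the p53 targets and the immediate early genes kept their calls without any 1 array, and each of the other 6 lost its call without at least 1 of the 6 control and 1 h arrays. Several of these medians moved by more than 1.5 times without 1 array. Without the A/J control they were -0.03 for mitosis, -0.14 for B cell, 0.40 for neutrophil and 0.34 for heart muscle genes, and without the A/J 1 h array 0.27 for p53 targets, -0.10 for mitosis, -0.35 for B cell and 0.31 for neutrophil genes. Leaving out the C57BL/6J 1 h array gave 0.09 for p53 targets, 0.12 for immediate early, 0.02 for matrix, 0.07 for heart muscle, -0.28 for macrophage and -0.08 for mitosis genes, and leaving out the C57BL/6J control gave -0.19 for macrophage and -0.09 for mitosis genes. The C3H/HeMs control left out gave 0.10 for p53 targets and -0.15 for mitosis genes, and the C3H/HeMs 1 h array left out gave 0.26 for matrix, 0.32 for heart muscle, -0.06 for macrophage and 0.05 for mitosis genes.

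In lung at 12 h, 8 named genes rose, each in all 3 strains. Cdkn1a stood 6.54-fold above the control (log2 2.71 ± 0.20 SE, n = 3 pools per group, limma adjusted p = 0.00158) and Ccng1 5.11-fold (2.35 ± 0.20, adjusted p = 0.0016). Exoc4, a subunit of the exocyst that tethers secretory vesicles, rose 3.80-fold (1.92 ± 0.15), Trp53inp1 3.70-fold (1.89 ± 0.19), Ephx1, the microsomal epoxide hydrolase, 3.49-fold (1.80 ± 0.14) and Ctsf, the lysosomal protease cathepsin F, 3.22-fold (1.69 ± 0.16). Sncg, gamma-synuclein, and Ccn5, a matricellular protein, rose 2.22-fold and 2.12-fold, and the adjusted p of the 8 genes ran from 0.00158 to 0.022. In C57BL/6J, whose arrays lie within the larger set, the changes were 2.45 for Cdkn1a, 2.18 for Ccng1, 1.67 for Exoc4, 1.66 for Trp53inp1, 1.51 for Ephx1, 1.33 for Ctsf, 0.88 for Sncg and 1.06 for Ccn5.

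The p53 targets rose as a list at 12 h in lung (median 0.77, adjusted p = 3.14e-11, and adjusted p = 0.764 with an estimated correlation). Adjusted over the list alone, 12 of the 20 members rose, 0 fell and 8 did not pass, and 4 passed over all features. B cell genes fell (16 measured, median -0.44, adjusted p = 3.6e-07, and adjusted p = 0.764 with an estimated correlation), with 7 falling, 0 rising and 9 not passing when adjusted over the list alone. Among them were Cd79a and Cd79b, the signalling chains of the B cell receptor, at -1.51 ± 0.38 and -1.06 ± 0.26 SE, H2-Ob, a chain of the class II chaperone of B cells, at -1.38 ± 0.30, and Fcmr, the receptor of immunoglobulin M, at -1.50 ± 0.38. T and NK cell genes fell (19 measured, median -0.43, adjusted p = 0.000203, and adjusted p = 0.78 with an estimated correlation). Of these, adjusted over the list alone, Il7r, the interleukin-7 receptor of lymphocytes, fell by 1.17 and Klrd1, an NK cell receptor, fell by 0.58, and 17 did not pass. Red cell genes fell as a list (9 measured, median -0.42, adjusted p = 0.0303, and adjusted p = 0.808 with an estimated correlation), with 0 members passing when adjusted over the list alone. The list medians in A/J, C57BL/6J and C3H/HeMs were 0.78, 0.28 and 0.79 for p53 targets, -0.92, -0.56 and -0.10 for B cell genes, -0.84, -0.20 and -0.23 for T and NK cell genes, and -1.08, 0.37 and -0.72 for red cell genes.

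The 10 features that passed at 12 h all rose, 8 of them with a gene symbol, and 1055 features had an unadjusted p under 0.05. With the set of the lung arrays as a block, an alternative chosen after seeing the data, 6 features passed, the median of p53 targets was 0.40, and the lists of T and NK cell genes and red cell genes were no longer called. This block also called DNA replication genes (median -0.14), heat shock genes (-0.20), glucocorticoid-induced genes (-0.46) and endothelium genes (-0.16) as lower at 12 h, where the medians without it were 0.02, 0.08, 0.15 and 0.01 (adjusted p = 0.672 with the block and an estimated correlation). With the 4 arrays left out, the 12 h group was 1 C57BL/6J array and the red cell median 0.04. Fitted with only the groups compared, or without A/J or C3H/HeMs, 0 features passed by limma, so that every gene call at 12 h was lost, and without C57BL/6J 6 passed. Without the C3H/HeMs 12 h array 6 features passed, and Trp53inp1 and Sncg were among those lost. Sncg was also lost without the C3H/HeMs control or the A/J control or 12 h array, Ccn5 without any 1 of 10 arrays, and the red cell list without the A/J control or 12 h array. The list medians were -0.26 for B cell and -0.19 for T and NK cell genes without the A/J control. For red cell genes they were -0.13 without the A/J 12 h, -0.70 without the C57BL/6J control and -0.74 without the C57BL/6J 12 h array.

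**Figure D1:**
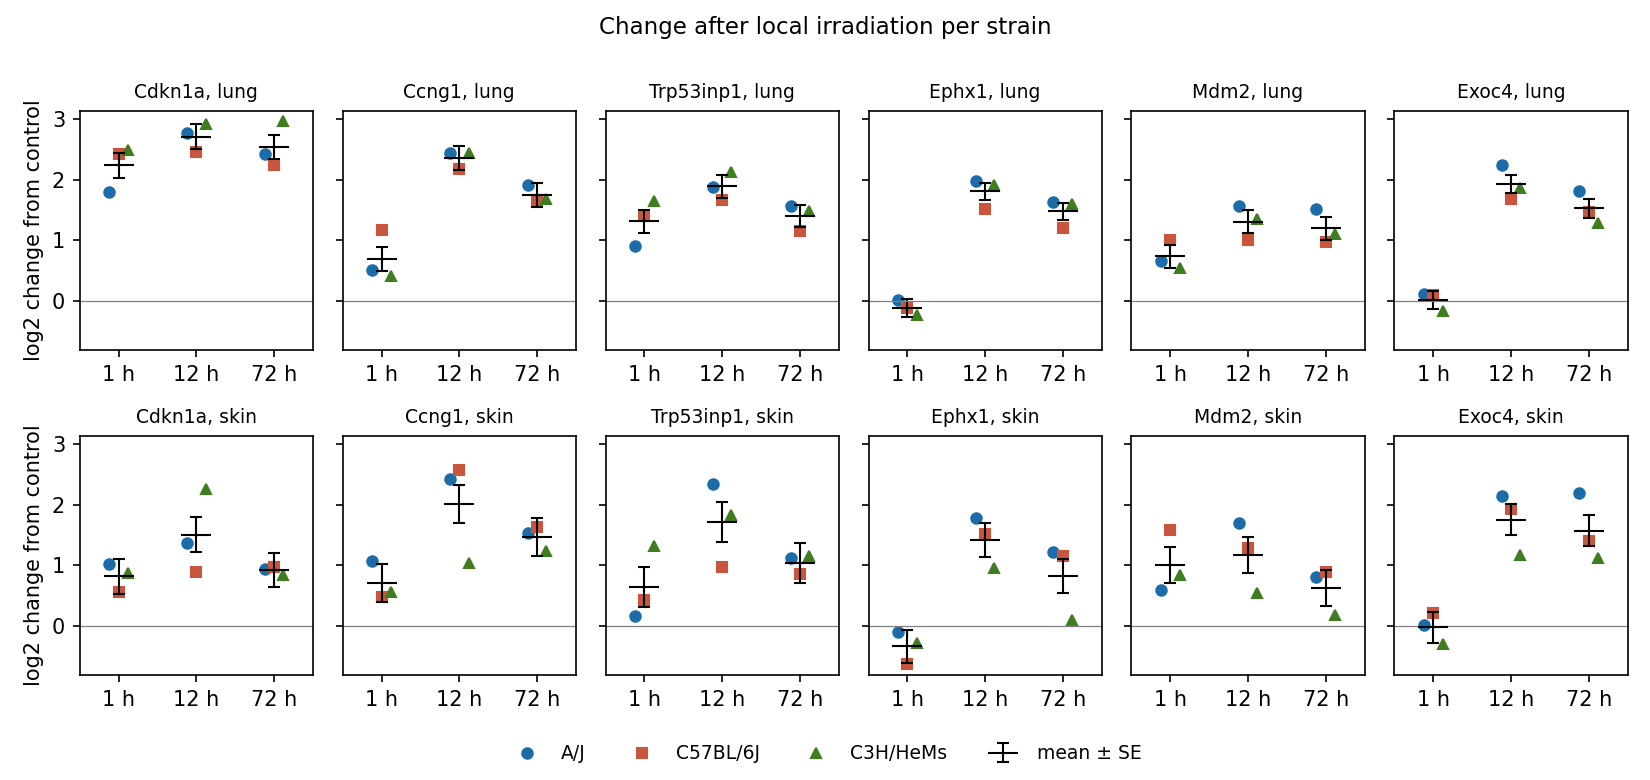
Points are log2 changes of Cdkn1a, Ccng1, Trp53inp1, Ephx1, Mdm2 and Exoc4 from the control of the same strain, 1 point per strain, at 1 h, 12 h and 72 h in lung and skin, with the mean and its SE from limma as bar and whiskers. Cdkn1a in lung lies between 1.79 and 2.96 in every strain and at every time, while Ccng1, at 0.69 in lung at 1 h, reaches 2.35 at 12 h.

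At 72 h, 6 named genes rose in lung and 1 fell, in all 3 strains. Cdkn1a was 5.81-fold above the control (log2 2.54 ± 0.20 SE, n = 3 pools per group, limma adjusted p = 0.00346), Ccng1 3.37-fold (1.75 ± 0.20, adjusted p = 0.0187), Exoc4 2.88-fold (1.52 ± 0.15) and Ephx1 2.78-fold (1.48 ± 0.14). Trp53inp1 rose 2.63-fold (1.40 ± 0.19, adjusted p = 0.0429) and Ctsf 2.42-fold (1.27 ± 0.16). H2-Eb1, a chain of the class II molecule that presents antigen to T cells, fell by 1.55 on the log2 scale (SE 0.22, adjusted p = 0.0482). The changes in C57BL/6J alone were 2.24 for Cdkn1a, 1.67 for Ccng1, 1.47 for Exoc4, 1.20 for Ephx1, 1.15 for Trp53inp1, 0.87 for Ctsf and -1.09 for H2-Eb1.

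The p53 targets were raised as a list in lung at 72 h (median 0.46, adjusted p = 3.6e-07, and adjusted p = 0.764 with an estimated correlation), with 8 rising, 0 falling and 12 not passing when adjusted over the list alone and 4 passing over all features. Its medians were 0.64 in A/J, 0.13 in C57BL/6J and 0.39 in C3H/HeMs, and 0.12 with the set of the lung arrays as a block. B cell genes were lower as a list (median -0.34, adjusted p = 5.6e-05, and adjusted p = 0.764 with an estimated correlation). Its medians were -0.89 in A/J, -0.22 in C57BL/6J and -0.20 in C3H/HeMs, and none of the 16 members passed when adjusted over the list alone. Cd79b was at -0.94 ± 0.26 SE. Mitosis genes fell (33 measured, median -0.18, adjusted p = 0.00593, and adjusted p = 0.939 with an estimated correlation). Aurka, the mitotic kinase Aurora A, fell by 1.28 (SE 0.25) as the single member to pass when adjusted over the list alone. Extracellular matrix genes rose (30 measured, median 0.17, adjusted p = 0.0447, and adjusted p = 0.939 with an estimated correlation), with Mmp2, a gelatin-cleaving protease, as the single riser when adjusted over the list alone (0.74 ± 0.17 SE).

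At 72 h 8 features rose and 2 fell, 7 of them named, and 1085 had an unadjusted p under 0.05. With the set of the lung arrays as a block 0 features passed by limma, and the mitosis and matrix lists were no longer called. The block also called DNA replication (median -0.18), oxidative stress (-0.14), heat shock (-0.21), glucocorticoid-induced (-0.78) and endothelium genes (-0.24) as lower, against medians of 0.0013, 0.14, 0.12, -0.26 and -0.12 without it (adjusted p = 0.672 with the block and an estimated correlation). The B cell list kept its call with the block. With the 4 arrays left out, the 72 h group was the single C57BL/6J array, and the B cell median was -0.20. Without the strain as a block 6 features passed. With only the groups compared, or without A/J or C3H/HeMs, 0 passed by limma, and without C57BL/6J 1 did. Leaving out 1 array gave 2 features without the A/J control, the A/J 72 h, the C3H/HeMs control or the C3H/HeMs 72 h array, 3 without the C57BL/6J 72 h array and 5 without the C3H/HeMs 1 h or 12 h array. Cdkn1a kept its call without any 1 array, H2-Eb1 lost it without each of the 12, and Trp53inp1, Ctsf, Ccng1, Exoc4 and Ephx1 lost it without 4 to 11 of them. The mitosis list was lost without the A/J control or 72 h array, and the matrix list without any 1 of 5 arrays, with medians of 0.13 to 0.30 in these repeats. Without the A/J 72 h array the medians were -0.16 for B cell, -0.03 for mitosis and 0.28 for matrix genes, without the C57BL/6J 72 h array -0.53, -0.30 and 0.30, and without the A/J control -0.07 for mitosis genes.

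Between 1 h and 72 h, Ephx1 and Exoc4 were higher in lung at the later time, by 1.59 ± 0.14 and 1.51 ± 0.15 on the log2 scale (SE, limma adjusted p = 0.0137 and 0.018). These 2 features passed, and 1047 had an unadjusted p under 0.05. When all 9 irradiated lung arrays were set against the 3 controls, Cdkn1a was the feature that passed, at 2.49 ± 0.19 (limma adjusted p = 0.000491), and 338 features had an unadjusted p under 0.05. The 72 h against 1 h count was 0 by limma with the set of arrays as a block, with only the groups compared and without A/J or C3H/HeMs, and 41 without C57BL/6J. It was 0 without the 1 h or 72 h array of A/J or C3H/HeMs or the C57BL/6J 72 h array, 1 without the C57BL/6J control or C3H/HeMs 12 h array and 6 without the C57BL/6J 1 h array. The count for all irradiated arrays was 8 without the A/J 1 h array and 0 by limma without C57BL/6J or C3H/HeMs.

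In skin 1 h after irradiation of the hind leg, inflammatory genes rose as a list (29 measured, median log2 change 0.55, adjusted p = 3.08e-15, and adjusted p = 0.148 with an estimated correlation), with medians of 0.71 in A/J, 0.91 in C57BL/6J and 0.32 in C3H/HeMs. Adjusted over the list alone, 6 members rose, 0 fell and 23 did not pass. These held Il1b, the cytokine interleukin-1 beta (3.45-fold, log2 1.79 ± 0.33 SE, n = 3 pools per group), Ccl7, a monocyte chemokine (2.14 ± 0.48), Icam1, a leukocyte adhesion molecule (1.03 ± 0.24), and Socs3, a feedback inhibitor of cytokine signals (1.43 ± 0.37). Wound keratinocyte genes rose (10 measured, median 0.94, adjusted p = 5.38e-08, and adjusted p = 0.148 with an estimated correlation), with medians of 0.45 in A/J, 1.91 in C57BL/6J and 0.41 in C3H/HeMs, and the list median was 0.49 without the C57BL/6J 1 h array. Within the list, adjusted over the list alone, Plaur, the urokinase receptor (1.37 ± 0.32), Itga5, a fibronectin-binding integrin chain (1.31 ± 0.33), and Serpinb2, a plasminogen activator inhibitor (1.81 ± 0.47), rose while 7 did not pass.

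Immediate early genes rose in skin at 1 h (24 measured, median 0.27, adjusted p = 1.19e-05, and adjusted p = 0.26 with an estimated correlation). The nuclear receptor Nr4a3 rose 6.09-fold (log2 2.61 ± 0.34 SE) and the AP-1 component Fosl1 10.4-fold (3.38 ± 0.63), adjusted over the list alone, and 22 did not pass. The p53 targets rose (median 0.14, adjusted p = 0.00045, and adjusted p = 0.248 with an estimated correlation). Of the 20 members Pmaip1, the pro-apoptotic protein Noxa, rose when adjusted over the list alone (1.47 ± 0.26), and Cdkn1a was at 0.82 ± 0.28. Mitosis genes fell (median -0.16, adjusted p = 0.0417, and adjusted p = 0.708 with an estimated correlation). Aurka fell by 1.35 (SE 0.23) as the single member to pass when adjusted over the list alone and the C3H/HeMs median was 0.46. Cholesterol synthesis genes (9 measured, median 0.38, adjusted p = 8.83e-05), mast cell genes (6, 0.52, adjusted p = 0.00386), extracellular matrix genes (30, 0.13, adjusted p = 0.00872) and DNA replication genes (29, 0.15, adjusted p = 0.00259) rose with no member passing when adjusted over the list alone. With an estimated correlation these 4 lists had adjusted p = 0.148, 0.258, 0.396 and 0.547. The medians in A/J, C57BL/6J and C3H/HeMs were 0.19, 1.15 and 0.09 for mast cell genes and 0.16, 0.19 and -0.04 for matrix genes. DNA replication genes, at -0.17, -0.07 and 0.78, were above 0 in 1 strain only. So were hair follicle genes, not called (-2.87, -1.08 and 2.81). Epidermal differentiation genes rose (15 measured, median 0.27, adjusted p = 0.000188, and adjusted p = 0.258 with an estimated correlation, but -0.11 under quantile scaling). The barrier lipoxygenase Alox12b was the single riser when adjusted over the list alone (1.22 ± 0.32). Heart muscle genes fell (13 measured, median -0.29, adjusted p = 0.0137, and adjusted p = 0.258 with an estimated correlation, but 0.07 under quantile scaling), with 0 members passing when adjusted over the list alone.

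No single feature passed over all 8750 in skin at 1 h by limma, with 382 at an unadjusted p under 0.05, where chance gives 438. One feature passed without the C3H/HeMs 72 h array. Smallest p-values among genes with a symbol belonged to Nr4a3 (limma adjusted p = 0.152), Aurka, Pmaip1, Il1b and Fosl1 (each of the last 4 adjusted p = 0.503). The call of the mast cell list was lost without the C57BL/6J control or 1 h array, the matrix list without the C57BL/6J control, and the p53 list without the C3H/HeMs 1 h array. The heart list lost it without the C57BL/6J 1 h or C3H/HeMs control array and the mitosis list without any 1 of 8 arrays. The median of DNA replication genes ran from -0.13 to 0.35 and was below 0 without the C3H/HeMs control or 1 h array (-0.01 and -0.06).

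Other list medians in skin at 1 h also moved by more than 1.5 times without 1 array. With the A/J control left out they were 0.23 for DNA replication, 0.21 for matrix, 0.41 for epidermal, -0.47 for heart muscle and -0.08 for mitosis genes. With the A/J 1 h array left out they were 0.28 for DNA replication, 0.64 for epidermal, -0.03 for mitosis genes and 0.37 for p53 targets. Leaving out the C57BL/6J control changed matrix genes to 0.07, mitosis genes to -0.01 and p53 targets to 0.30. Leaving out the C57BL/6J 1 h array changed immediate early genes to 0.12, mast cell genes to 0.26, p53 targets to 0.21, epidermal genes to 0.13, DNA replication genes to 0.26, heart muscle genes to -0.18 and mitosis genes to -0.05. Without the C3H/HeMs control matrix genes were at 0.22 and mitosis genes at -0.37, and without the C3H/HeMs 1 h array p53 targets were at 0.04, heart muscle genes at -0.46 and mitosis genes at -0.37.

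In skin at 12 h, inflammatory genes were higher and mitosis genes lower. The inflammatory list rose (29 measured, median log2 change 1.06, adjusted p = 2.39e-21, and adjusted p = 0.148 with an estimated correlation), with 16 members rising, 0 falling and 13 not passing when adjusted over the list alone. Il1b rose 3.30-fold (log2 1.72 ± 0.33 SE, n = 3 pools per group), Serpina3n, a protease inhibitor of the acute phase, 3.07-fold (1.62 ± 0.31), Icam1 2.18-fold (1.12 ± 0.24) and Ccl7 4.79-fold (2.26 ± 0.48). The mitosis list fell (33 measured, median -0.84, adjusted p = 9.66e-21, and adjusted p = 0.186 with an estimated correlation). In all, 21 members fell, adjusted over the list alone, 0 rose and 12 did not pass, and the medians were -0.82 in A/J, -1.24 in C57BL/6J and -0.67 in C3H/HeMs. Among them the mitotic kinesin Kif20a fell by 1.25 (SE 0.24), the spindle protein Nusap1 fell by 1.32 (SE 0.26), Cks2, a partner of cyclin-dependent kinases, fell by 1.29 (SE 0.26) and the kinetochore protein Cenpf fell by 1.44 (SE 0.30).

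The p53 targets rose in skin at 12 h (median 0.77, adjusted p = 4.39e-12, and adjusted p = 0.148 with an estimated correlation), with 9 of 20 rising, 0 falling and 11 not passing when adjusted over the list alone. Dcxr, a carbonyl reductase, rose 4.74-fold (log2 2.24 ± 0.27 SE), Ccng1 4.05-fold (2.02 ± 0.31), Pmaip1 3.10-fold (1.63 ± 0.26) and Cdkn1a 2.84-fold (1.51 ± 0.28). Interferon-stimulated genes rose as a list (19 measured, median 0.80, adjusted p = 1.07e-10, and adjusted p = 0.26 with an estimated correlation). None passed when adjusted over the list alone, with Ifit1 at 1.29 ± 0.34 and Irf7, a transcription factor of the interferon response, at 1.16 ± 0.43. Macrophage and monocyte genes rose (15 measured, median 0.47, adjusted p = 3.5e-06, and adjusted p = 0.396 with an estimated correlation). Its medians were 0.44 in A/J, 1.55 in C57BL/6J and -0.00 in C3H/HeMs, and none passed when adjusted over the list alone. Cd163, a scavenger receptor, was at 1.15 ± 0.37. Of the 9 neutrophil genes (median 0.22, adjusted p = 0.0146, and adjusted p = 0.248 with an estimated correlation) Csf3r rose when adjusted over the list alone (1.53 ± 0.42). Of the 10 wound keratinocyte genes (median 0.60, adjusted p = 0.000568, and adjusted p = 0.258 with an estimated correlation) Slpi, a protease inhibitor of epithelia, rose (1.66 ± 0.44).

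Further lists moved in skin at 12 h without a member passing when adjusted over the list alone. DNA replication genes (29 measured, median -0.35, adjusted p = 0.00018) and heart muscle genes (13, -0.42, adjusted p = 0.00114) fell, while endothelium genes (17, 0.29, adjusted p = 0.0108) and adipocyte and lipid synthesis genes (14, 0.35, adjusted p = 0.0416) rose. With an estimated correlation these 4 lists had adjusted p = 0.396, 0.207, 0.64 and 0.611. The medians in A/J, C57BL/6J and C3H/HeMs were -0.01, 0.68 and -0.20 for endothelium genes, 0.14, 0.99 and -0.71 for adipocyte genes and -0.30, -0.52 and 0.01 for DNA replication genes, so the first 2 rose through C57BL/6J. Skeletal muscle genes fell as a list (18, -0.73, adjusted p = 0.00136, and adjusted p = 0.64 with an estimated correlation), with medians of 0.59 in A/J, -0.33 in C57BL/6J and -2.59 in C3H/HeMs. On the C3H/HeMs control array the skeletal muscle list stood at a median log2 ratio of 0.88, against 0.04 on the C57BL/6J control and -1.36 on the A/J control.

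At 12 h in skin 0 features passed over all 8750 by limma, with 587 at an unadjusted p under 0.05. Dcxr came nearest (limma adjusted p = 0.0791), followed among genes with a symbol by Abcb1b, a drug efflux pump (log2 1.76 ± 0.25 SE, adjusted p = 0.142), Exoc4 (1.75 ± 0.25, adjusted p = 0.142), Ccng1 (adjusted p = 0.144) and Gsto1, a glutathione transferase (1.44 ± 0.23, adjusted p = 0.144). The skeletal muscle call was lost without the C3H/HeMs control or 12 h array (medians -1.54 to 0.15 over these repeats). The macrophage call was lost without the C57BL/6J 12 h array, the neutrophil call without the C3H/HeMs control and the endothelium and adipocyte calls without the A/J control or C57BL/6J control. Without the C57BL/6J 12 h array the medians were -0.08 for endothelium, -0.07 for adipocyte and 0.94 for wound keratinocyte genes, and without C57BL/6J the adipocyte median was -0.17. Without the C3H/HeMs 12 h array they were -0.12 for skeletal muscle, 0.76 for macrophage, 0.53 for neutrophil and 0.33 for wound keratinocyte genes, and without the C3H/HeMs control -0.16 for skeletal muscle, 0.89 for macrophage, 0.09 for neutrophil and -0.54 for DNA replication genes. Leaving out the C57BL/6J control gave 0.23 for macrophage, 0.35 for neutrophil, 0.13 for endothelium and -0.23 for DNA replication genes. Leaving out the A/J control gave -1.13 for skeletal muscle, 0.18 for endothelium and -0.22 for DNA replication genes, and the A/J 12 h array left out gave -1.31 for skeletal muscle genes. One feature passed without the A/J 12 h, the C3H/HeMs 12 h or the C3H/HeMs 72 h array.

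**Figure D2:**
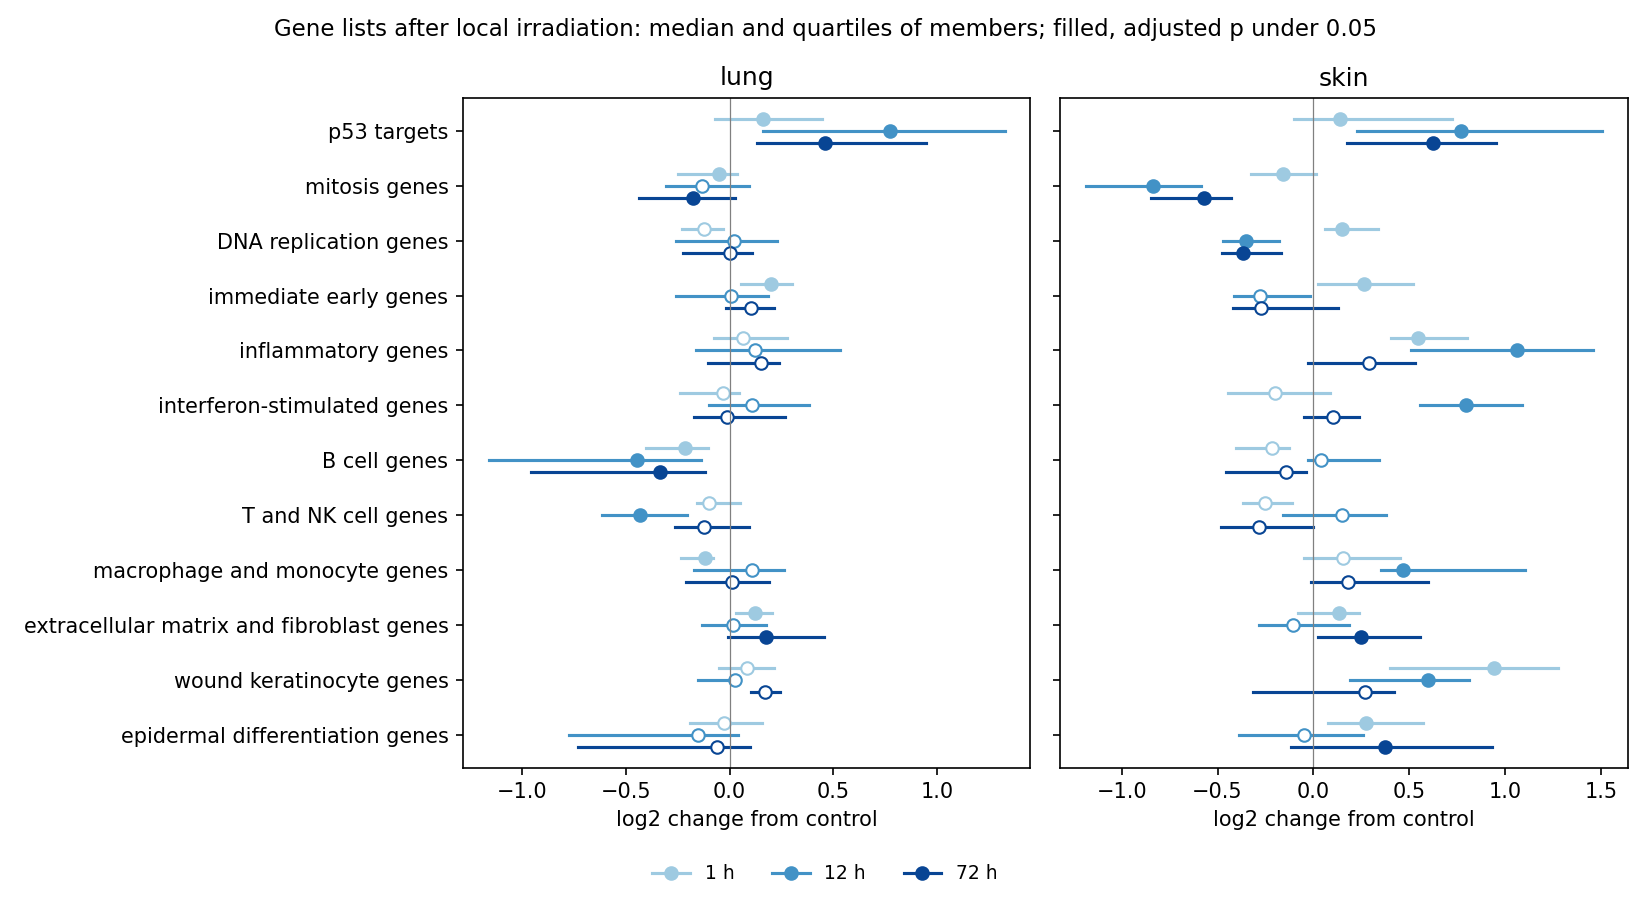
Points are the median log2 change of the measured members of 12 gene lists, with the quartiles as whiskers, at 1 h, 12 h and 72 h in lung and skin; filled points have an adjusted p under 0.05 with the preset correlation. In skin at 12 h the inflammatory list lies at 1.06 and the mitosis list at -0.84, and the p53 targets lie at 0.77 in each tissue at that time.

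At 72 h in skin the mitosis genes remained lower than in the controls as a list (median log2 change -0.57, adjusted p = 2.5e-11, and adjusted p = 0.258 with an estimated correlation). Adjusted over the list alone, 9 members fell, 1 rose and 23 did not pass. Aurka fell by 1.05 (SE 0.23, n = 3 pools per group), the survivin gene Birc5 fell by 1.07 (SE 0.28) and the topoisomerase gene Top2a fell by 1.14 (SE 0.31), while Ube2c, a ubiquitin-conjugating enzyme of mitotic exit, rose by 1.07 (SE 0.29). The p53 targets rose (median 0.63, adjusted p = 1.41e-07, and adjusted p = 0.148 with an estimated correlation). Of its members, adjusted over the list alone, 9 rose, 0 fell and 11 did not pass, among the risers Ccng1 (2.77-fold, log2 1.47 ± 0.31), Dcxr (1.34 ± 0.27), the translesion polymerase Polk (1.23 ± 0.37) and Pmaip1 (0.91 ± 0.26). Epidermal differentiation genes rose (15 measured, median 0.37, adjusted p = 0.00292, and adjusted p = 0.38 with an estimated correlation). Adjusted over the list alone, Klk5, a protease of shedding skin (1.11 ± 0.25), Lor, the cornified envelope protein loricrin (1.14 ± 0.29), and Krt10 (1.24 ± 0.32) rose while 12 did not pass.

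Hair follicle genes fell as a list in skin at 72 h (6 measured, median -2.16, adjusted p = 0.00123, and adjusted p = 0.396 with an estimated correlation). The medians were -3.11 in A/J, -3.16 in C57BL/6J and 1.92 in C3H/HeMs, whose control array had a list level of 0.40 against 3.67 and 4.81 on the A/J and C57BL/6J controls. Crym, which binds thyroid hormone, fell by 2.14 (SE 0.41) and the root sheath keratin Krt71 by 2.18 (SE 0.75), in all 3 strains. Only these passed when adjusted over the list alone. Heat shock and unfolded protein genes fell (17 measured, median -0.38, adjusted p = 7.16e-05, and adjusted p = 0.148 with an estimated correlation), as did DNA replication genes (29, -0.37, adjusted p = 0.00018), skeletal muscle genes (18, -0.75, adjusted p = 0.00872), glucocorticoid-induced genes (8, -0.48, adjusted p = 0.0129) and heart muscle genes (13, -0.50, adjusted p = 0.0129). With an estimated correlation the last 4 had adjusted p = 0.396, 0.708, 0.248 and 0.258. Extracellular matrix genes (30, 0.25, adjusted p = 0.00259) and mast cell genes (6, 0.53, adjusted p = 0.00452) rose, with adjusted p = 0.379 and 0.258 with an estimated correlation. No member of these 7 lists passed when adjusted over the list alone. Skeletal muscle medians were 0.34 in A/J, -0.27 in C57BL/6J and -2.01 in C3H/HeMs. In values, the chaperone gene Hsph1 was at -0.68 ± 0.20 SE, Uhrf1, which maintains DNA methylation in S phase, at -1.09 ± 0.34 and Mmp2 at 0.92 ± 0.25.

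At 72 h in skin 0 features passed by limma, with 647 at an unadjusted p under 0.05. Among genes with a symbol the smallest p-values belonged to Exoc4 (log2 1.57 ± 0.25 SE, limma adjusted p = 0.52), Gsto1 (1.28 ± 0.23), the ubiquitin ligase gene Trim8 (1.08 ± 0.20), Crym and the secretoglobin gene Scgb3a1 (1.05 ± 0.20), the last 4 with adjusted p = 0.561. The hair follicle and glucocorticoid calls were lost without the A/J 72 h array (medians -3.09 to -0.81 and -0.58 to -0.28 over these repeats). The skeletal and heart muscle calls were lost without the C3H/HeMs control or 72 h array, the matrix call without the C57BL/6J control or 72 h array and the mast cell call without the C57BL/6J control. Without the C3H/HeMs control the medians were -0.11 for skeletal muscle and -0.86 for mitosis genes, and without the C3H/HeMs 72 h array -0.35 for skeletal and -0.28 for heart muscle genes. They were -1.14 for hair follicle genes without the A/J 72 h array, -0.28 for glucocorticoid-induced genes without the C57BL/6J 72 h array and -0.16 for DNA replication genes without the C57BL/6J control. One feature passed without the A/J 72 h array.

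**Figure D3:**
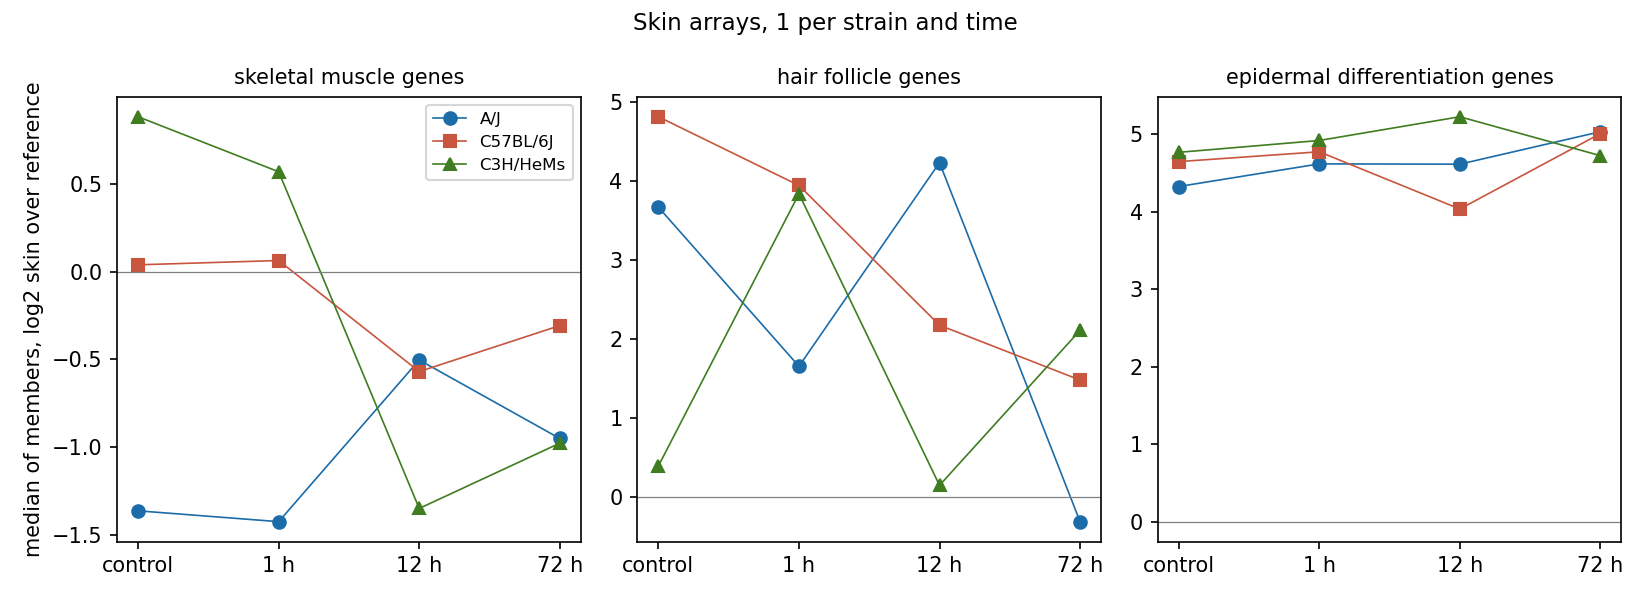
Each point is the median log2 ratio to the reference of the skeletal muscle, hair follicle or epidermal differentiation list on 1 skin array, by strain and time. The skeletal muscle list runs from 0.88 in the C3H/HeMs control to -1.35 at 12 h in that strain, the hair follicle list from -0.31 to 4.81, and the epidermal list stays between 4.04 and 5.23.

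Comparing 72 h with 1 h in skin gave 0 features by limma, with 745 at an unadjusted p under 0.05 and a smallest adjusted p of 0.162, and 1 feature without the A/J 72 h or the C3H/HeMs 1 h array. When the 9 irradiated skin arrays were set against the 3 controls, 0 features passed by limma, with 412 at an unadjusted p under 0.05 and a smallest adjusted p of 0.742.

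No feature passed the test in lung and skin at the same time, at any of the 3 times, except 1 at 12 h without the C3H/HeMs 12 h skin array and 1, Exoc4, at 12 h with only named genes tested. By the rule fixed for genes in common, the largest changes shared at 12 h were those of Ccng1 (log2 2.35 in lung and 2.02 in skin), the neutrophil calcium-binding protein S100a8 (1.83 and 1.79), Exoc4 (1.92 and 1.75), Trp53inp1 (1.89 and 1.72) and Serpina3n (1.52 and 1.62). Next at 12 h came Cdkn1a (2.71 and 1.51), Slfn4, a schlafen gene of myeloid cells (1.43 and 2.02), Ephx1 (1.80 and 1.42), Pmaip1 (1.38 and 1.63) and Ctsf (1.69 and 1.18). At 72 h they were Exoc4 (1.52 and 1.57), Ccng1 (1.75 and 1.47), H2-Eb1 (-1.55 and -1.12), Aurka (-1.28 and -1.05) and Trp53inp1 (1.40 and 1.04). Next at 72 h came Ctsf (1.27 and 1.01), H2-Aa, a chain of another class II molecule (-1.15 in skin), the 14-3-3 gene Ywhag (-0.94 and -0.97), Cdkn1a (2.54 and 0.92) and the calcium channel subunit gene Cacng4 (-1.17 and -0.88). At 1 h they were the neurofilament gene Nefm (-1.59 and -1.25), Noxred1 (-1.16 and -1.13), the apolipoprotein gene Apoc4 (-1.05 and -1.15), Gulo of vitamin C synthesis (-1.01 and -1.07) and Aurka (-0.99 and -1.35). Next at 1 h came the neuronal gene Cend1 (-0.87 and -0.94), Cdkn1a (2.23 and 0.82), the clock repressor Nr1d2 (-0.82 and -0.80), S100b, a glial calcium-binding protein (-0.81 and -0.80), and Nr4a3 (0.80 and 2.61). Of the values in skin none passed over all features, and in lung only those given above did.

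Some of these shared changes moved by more than 1.5 times without 1 array. In lung at 1 h, without the A/J control, Noxred1 was at -0.42, Apoc4 at -0.67, Gulo at -0.48, Cend1 at -0.53 and S100b at -0.43. Without the A/J 1 h array Nr1d2 was at -0.43 and Nr4a3 at 1.27, without the C57BL/6J control Gulo was at -1.53 and Cend1 at -1.33, without the C57BL/6J 1 h array Apoc4 was at -0.69, and without the C3H/HeMs 1 h array Nr4a3 was at 0.44 and S100b at -0.53. In skin at 1 h, without the C3H/HeMs 1 h array, Nefm was at -0.74, Noxred1 at -0.65, Gulo at -0.69 and Cend1 at -0.52, and without the A/J 1 h array Nr1d2 was at -0.48. S100a8 in skin at 12 h was at 1.02 without the C3H/HeMs 12 h array. At 72 h Cacng4 in lung was at -0.67 without the A/J control and -0.73 without the A/J 72 h array, and Ywhag was at -0.56 in lung without the A/J 72 h array and at -0.29 in skin without the C3H/HeMs 72 h array.

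The mean of the lung and skin responses, a test added after seeing the data, called 36 features up and 3 down at 12 h. The largest rises were Ccng1 (log2 2.18 ± 0.19 SE, limma adjusted p = 1.61e-05), Cdkn1a (2.11 ± 0.18, adjusted p = 1.43e-05), Exoc4 (1.84 ± 0.15, adjusted p = 1.38e-05), Trp53inp1 (1.80 ± 0.20, adjusted p = 0.00011) and Ephx1 (1.61 ± 0.16, adjusted p = 4.12e-05). The mitotic genes Cks2, Nusap1 and Kif23 fell by 0.75, 0.74 and 0.61. At 72 h 13 features were up and 4 down, led by Cdkn1a (1.73 ± 0.18), Ccng1 (1.61 ± 0.19), Exoc4 (1.55 ± 0.15), Trp53inp1 (1.22 ± 0.20) and Ephx1 (1.15 ± 0.16). Falls at 72 h were those of H2-Eb1 (-1.33 ± 0.19, limma adjusted p = 0.00382), Aurka (-1.16 ± 0.17, adjusted p = 0.00382) and Tor2a, a torsin ATPase (-0.94 ± 0.16, adjusted p = 0.0175). At 1 h Cdkn1a rose (1.53 ± 0.18, adjusted p = 0.00232) and Aurka fell by 1.17 (SE 0.17, adjusted p = 0.0183). A change in the mean can rest on 1 tissue. Leaving out the 4 lung arrays (1 left each at 12 h and 72 h) gave 1 feature by limma at 1 h. Without A/J, C57BL/6J or C3H/HeMs the counts were 0, 0 and 0 at 1 h, 14, 13 and 15 at 12 h and 0, 7 and 6 at 72 h by limma. Single arrays moved these counts too. At 1 h 9 features passed without the C3H/HeMs 1 h skin array, 4 without the A/J 1 h array of lung or skin, and 1 without the A/J lung control, either C3H/HeMs control, the C3H/HeMs 1 h lung array or the C57BL/6J control or 1 h skin array. At 12 h 22 passed without the A/J 12 h lung array and 24 without the C3H/HeMs control or 12 h lung array or the A/J or C57BL/6J skin control. At 72 h 11 passed without the A/J 72 h lung array or the C3H/HeMs lung control.

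The test of the difference between the skin and lung responses called 0 features by limma at 1 h, 12 h and 72 h, with 176, 737 and 1121 at an unadjusted p under 0.05. At 12 h 2 features passed without the A/J skin control and 1 without the C3H/HeMs 12 h or 72 h skin array. At 72 h 3 passed without the C57BL/6J 72 h skin array, 2 without the A/J 72 h skin array and 1 without the C57BL/6J lung control or the A/J 12 h skin array. Dose, irradiated site and dye differ with the tissue and cannot be separated from it. Among the lists, 27 of 84 tests differed between tissues, and 0 of 84 with an estimated correlation. Inflammatory genes were higher in skin relative to lung by a median of 0.54 at 1 h (adjusted p = 1.56e-12, and adjusted p = 0.12 with an estimated correlation) and 0.85 at 12 h (adjusted p = 1.47e-11, and adjusted p = 0.124 with an estimated correlation). Mitosis genes differed by -0.77 at 12 h (adjusted p = 4.36e-09, and adjusted p = 0.463 with an estimated correlation), interferon-stimulated genes by 0.78 (adjusted p = 1.8e-06, and adjusted p = 0.529 with an estimated correlation) and B cell genes by 0.62 (adjusted p = 9.8e-06, and adjusted p = 0.529 with an estimated correlation). The p53 targets did not pass this test at 1 h, 12 h or 72 h (adjusted p = 0.868, 0.813 and 0.898).

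Counts without a model gave changes of at least 2-fold in the same direction in all 3 strains. In lung such features numbered 2 up and 1 down at 1 h, 13 up and 2 down at 12 h and 7 up and 15 down at 72 h. In skin they numbered 9 up and 2 down, 22 up and 4 down and 16 up and 7 down. Independent lists would give fewer than 1 in each of these counts. That number takes the strains as independent and all features as equally variable. In lung the changes of A/J and C3H/HeMs correlated at 0.36 at 12 h and 72 h, and those of either with C57BL/6J at -0.11 to 0.04. Counts above it thus do not by themselves show a response shared by the strains. At 12 h 5 features were up in lung as well as skin (Exoc4, Serpina3n, Ccng1, Ctsf and 1 without a symbol), where 0.0327 would be shared by independent lists (Fisher's exact p = 7.84e-11). At 72 h these were Exoc4 and Ccng1 (0.0128, Fisher's exact p = 6.55e-05), and none was shared at 1 h. Skin features at 12 h held Lcn2 (log2 1.27 to 2.86), Timp1 (1.23 to 2.95) and Ccl9 (1.83 to 2.98), and skin at 72 h held falls of Mki67 (-1.35 to -1.01), the tight junction gene Cldn1 (-1.73 to -1.05) and Selenbp1 (-1.23 to -1.09). In lung at 72 h the trefoil factor Tff2 (-1.95 to -1.38) and the checkpoint mediator Clspn (-1.62 to -1.11) were lower. These 8 genes were chosen after their values were seen. With a symbol, 5 features were up and 3 down in lung at 72 h and 6 up and 7 down in skin at 72 h, and at 1.5-fold 34 features were up and 43 down in lung at 12 h, so the balance of rises and falls turned with these choices. Of the 22 lung features at 72 h 14 had no symbol, and 10 features in all were counted when probes with a ratio of exactly 0 were left out.

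Strains differed in 258 features in lung and 33 in skin, over all times, by limma's F test. In lung the smallest p of a named gene was that of Pianp, which binds an inhibitory immune receptor. Its mean log2 ratios were -0.28 ± 0.13 in A/J, -2.82 ± 0.29 in C57BL/6J and -0.49 ± 0.09 in C3H/HeMs (SD, n = 4 arrays each, limma adjusted p = 7.79e-05). Next came the actin regulator Cap1 (0.11, -1.99 and 0.12) and Map2, a microtubule protein of neurons (-1.13, -3.01 and -0.98). Hddc3 (-0.45, -1.93 and -0.28) and the complement inhibitor Cd59a (-1.05, -1.56 and -0.03) followed. In skin the named genes with the smallest p were the carbonic anhydrase Car3 (1.30 ± 0.16, -1.76 ± 0.13 and 1.56 ± 0.80, adjusted p = 0.00302) and Pianp (0.93, -1.19 and 0.69). Next came the zinc finger Zfp945 (-0.34, 1.27 and 1.43), the myeloperoxidase Mpo (1.77, -1.10 and 0.46) and the tetraspanin Tspan8 (-1.23, 0.70 and 1.20). By pair, 322 lung features differed between C57BL/6J and A/J, 159 between C3H/HeMs and C57BL/6J and 37 between C3H/HeMs and A/J. In skin the numbers were 31, 16 and 22. The lung arrays that stand apart hold none of C57BL/6J, so the lung counts with C57BL/6J carry the difference between the sets. With the set as a block the lung pairs gave 40, 42 and 70 features, in another order. With the 4 arrays left out only 2 residual degrees of freedom remained, too few for a count to say much. With the set of lung arrays as a block 91 lung features passed, and without any 1 of the 12 lung arrays between 54 and 172. In skin 459 passed without the C3H/HeMs 12 h array, 91 without the A/J 12 h array, 36 without the C3H/HeMs 72 h array and 5 to 20 without any other 1 array. Without A/J, C57BL/6J or C3H/HeMs 64, 0 and 17 lung features and 3, 0 and 59 skin features passed by limma.

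The response to irradiation differed between strains in 2 lung features and 0 skin features by limma, with 197 and 293 at an unadjusted p under 0.05. The lung features were Sh3bp2, an adaptor protein of immune cells (limma adjusted p = 0.00731), and a probe without a symbol (adjusted p = 5.2e-05). For each of them the difference lay in the single C3H/HeMs control array, where Sh3bp2 had a log2 ratio of -5.42 against -0.81 to 0.14 on the other 11 lung arrays. The lung count was 0 without C3H/HeMs, 1 without A/J or C57BL/6J and 5 without the A/J 1 h array. In skin the smallest p was that of Sectm1b (limma adjusted p = 0.0703).

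Several lists fixed in advance did not pass at any time in either tissue in the fits without the set of the lung arrays. DNA repair genes (13 measured) had medians between -0.20 and 0.04 with a smallest adjusted p of 0.111, oxidative stress and metallothionein genes (20) between -0.11 and 0.27 with 0.0599, and smooth muscle genes (10) between -0.34 and 0.10 with 0.114. Lung epithelium genes (9) lay in lung between -0.14 and 0.29 with 0.0616. With the set as a block, oxidative stress genes were called lower in lung at 72 h, as given above. Lung epithelium (-0.14) and DNA replication genes (-0.12) were called lower at 1 h, each with adjusted p = 0.672 with an estimated correlation. Circadian clock genes (13) had medians between -0.19 and 0.28 with a smallest adjusted p of 0.112. Their members went both ways at 1 h, when in lung the clock output genes Nr1d2, Per3 and Hlf were at -0.82, -0.75 and -0.89 and the core activator Arntl at 0.99, and in skin at -0.80, -0.63, -0.54 and 0.47. Arntl was above the control in every strain in lung, and in skin it was at -0.17 in C3H/HeMs. Over all lists, 16 of 84 tests in lung and 34 of 84 in skin passed with the preset correlation, and 0 of 168 with an estimated correlation. Without the C3H/HeMs lung control 25 tests passed in lung.

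**Figure D4:**
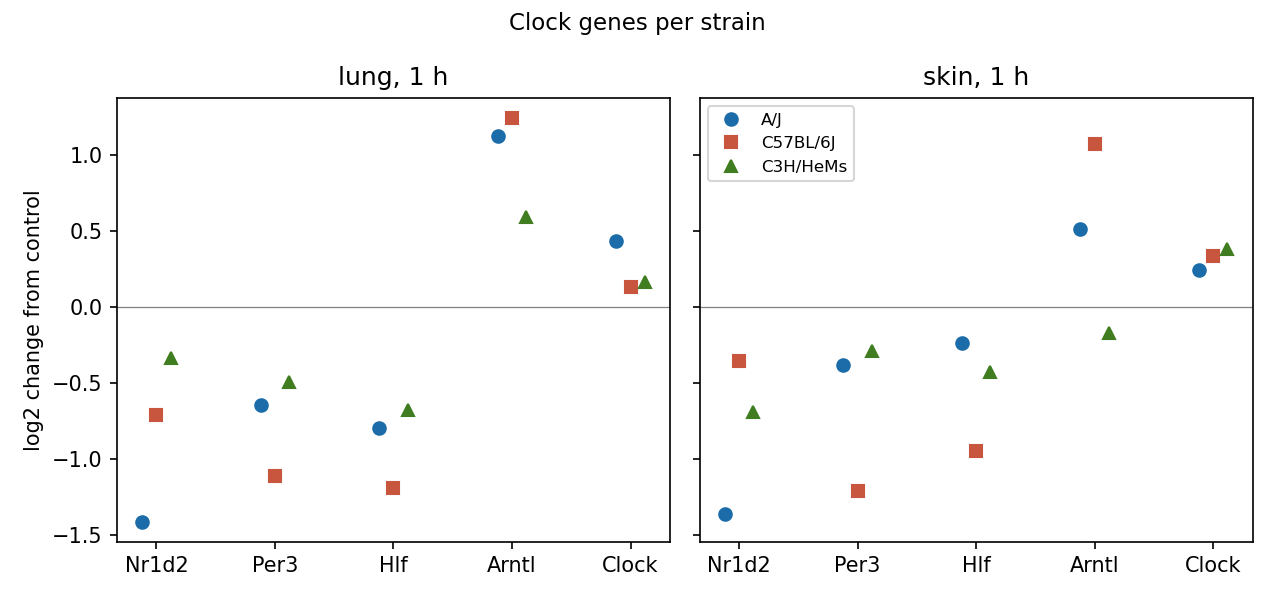
Points are log2 changes at 1 h from the control of the same strain for the clock output genes Nr1d2, Per3 and Hlf and the core genes Arntl and Clock in lung and skin, 1 point per strain. The 18 values of the output genes lie below 0, from -1.41 to -0.24, those of Clock lie above 0, from 0.13 to 0.43, and those of Arntl lie above 0 except for -0.17 in skin of C3H/HeMs.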

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

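For the sets of lung arrays every test was chosen only after the result was seen, and for the muscle genes the test of a response shared by the 3 strains was.

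Within a strain and tissue, single arrays stood off for 2 of the strain genes. Hddc3 in C57BL/6J lung had a log2 ratio of -1.73 at 72 h against -2.01 to -1.97 on the other 3 arrays, a gap of 0.867 of the range, and Car3 in C3H/HeMs skin had 2.75 in the control against 1.03 to 1.32 after irradiation, a gap of 0.833. Both gaps lie above Dixon's critical value for 4 arrays. Chance passes it in about 1 in 20 groups, and 30 groups were tested.

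Sh3bp2 and a probe without a symbol responded differently to irradiation in the 3 strains in lung, by a test of the interaction (limma adjusted p = 0.00731 and 5.2e-05). The change of Sh3bp2 was -0.27 in A/J, 0.01 in C57BL/6J and 5.16 in C3H/HeMs. Each difference came from the C3H/HeMs control array alone.

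The 12 h and 72 h lung arrays of A/J and C3H/HeMs stood apart from the other 8. Neither C57BL/6J array of those times lay on their side (0 of them), which argues against a response shared by the 3 strains as the whole cause. Each of the 4 arrays had at least 115 probes with a ratio of exactly 0, against at most 23 on the others, so signal near background or a different processing of these arrays may be the source. A response in the lung tissue of A/J and C3H/HeMs alone cannot be told apart from this, since the lowest median change of 33 genes of liver, brain, testis and kidney was -0.67 in A/J while C3H/HeMs had 0.30 and 0.35. On the other 5 irradiated lung arrays these medians lay between -0.13 and 0.28, so the C3H/HeMs values are little above them. No date or batch of the arrays was given in the sources used here.

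Skeletal muscle genes were lower in skin at 12 h and 72 h as a list, through C3H/HeMs (adjusted p = 0.64 and 0.708 with an estimated correlation). Of the 18 members, 88.9% were at least 2-fold below the control at 12 h in C3H/HeMs, against 1 in C57BL/6J and 0 in A/J, and these genes moved together as different amounts of leg muscle in the pooled skin may bring about. The A/J median at 12 h was 0.59, which argues against a response to irradiation shared by the 3 strains. A response of muscle in C3H/HeMs alone was not tested.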

How the results depend on the processing

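Tests with the set of lung arrays as a block, without the 4 lung arrays, without probes at the limit, without exact zeros and with only named genes were chosen only after the results were seen. Of 73 gene values, 72 kept direction and call uncentred, 73 under quantile scaling, 73 with every probe its own feature, 72 of 72 without exact zeros, 73 without probes at the limit and 70 with trend and robust moderation. Without the strain block 68 kept it and 5 lost a call, and with only named genes 69 kept it, where 4 skin genes gained a call. A value not called at first counts as kept where its direction holds, and no skin gene value was called at first. Of 33 lung gene values, 23 kept direction and call with the set as a block and 17 with the 4 arrays left out. Of 50 list calls, 37 held under quantile scaling, 47 with only named genes and 48 to 50 uncentred, with every probe its own feature, without exact zeros, without the strain block and with trend and robust moderation. Without probes at the limit 48 of 49 held. Without A/J, C57BL/6J or C3H/HeMs 44, 35 and 42 held, and 3 medians turned without C57BL/6J and 3 without C3H/HeMs. Of 16 lung list calls, 12 held with the set as a block and 11 with the 4 arrays left out. With the block 11 further lung list tests passed, all 11 as falls and 7 with a median that turned. Its late shift rests on C57BL/6J, and 0 of its list tests passed with an estimated correlation. As deposited, without centring, the median of all features shifted by 0.12 and 0.11 in lung at 12 h and 72 h and by under 0.06 elsewhere.

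Under 1.5-fold instead of 2-fold, 20, 77 and 145 lung features and 72, 124 and 131 skin features passed in all 3 strains, with 34 up and 43 down in lung at 12 h. With only the groups compared, lung had 0 features at 1 h, 12 h, 72 h and 72 h against 1 h by limma. With an estimated correlation 0 lists were called. With the 4 lung arrays left out (1 array left per late lung group), the red cell median at 12 h turned to 0.040. With the set as a block, lung had 6 at 12 h, 0 at 72 h, 0 for 72 h against 1 h and 91 for strains, and the mean 9 at 12 h and 5 at 72 h. Without the strain block lung had 6 at 72 h and the mean 25 at 12 h, and no other count moved as far. With every probe its own feature, lung 72 h against 1 h gave 5 and skin strains 52. Without exact zeros, 10 lung features were 2-fold at 72 h, and lung gave 4 for 72 h against 1 h and 2 for all irradiated arrays. Without probes at the limit the lung interaction gave 1. With only named genes, 9 and 8 lung features were 2-fold at 12 h and 72 h (5 up and 3 down at 72 h) and 13 in skin at 72 h (6 up and 7 down), with 1 common at 12 h; lung gave 5 for 72 h against 1 h, 2 for all irradiated arrays and 1 for the interaction, and skin 1 at 1 h, 3 at 12 h, 1 for 72 h against 1 h, 1 for the interaction and 54 for strains. Under quantile scaling, lung gave 6 for 72 h against 1 h, 3 of them up and 3 down, and 2 for all irradiated arrays, the mean at 1 h gave 1, and medians turned at 1 h to 0.0056 for lung mitosis genes, -0.11 for skin epidermal genes and 0.071 for skin heart muscle genes. The split into up and down also moved: uncentred, lung at 72 h had 8 up and 0 down, and 2-fold skin features at 72 h 17 up and 3 down; under quantile scaling 2-fold lung features at 12 h had 9 up and 4 down and the mean at 12 h 37 up and 8 down. With trend and robust moderation the mean at 1 h gave 1 and skin at 12 h 1. The alternative for missing values was not run, as none was missing.

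Leaving out each strain and each array in turn gave 0 to 1 lung features at 1 h, 0 to 10 at 12 h, 0 to 8 at 72 h, 0 to 41 for 72 h against 1 h, 0 to 8 for all irradiated arrays, 0 to 172 for strains, 0 to 5 for the interaction and 13 to 25 lung lists. Skin gave 0 to 1 at 1 h, at 12 h, at 72 h and for 72 h against 1 h, 0 to 459 for strains and 30 to 42 lists. Skin minus lung gave 0 to 2 at 12 h and 0 to 3 at 72 h, the mean 0 to 9, 13 to 51 and 0 to 21, and the count in common 0 to 1 at 12 h. Medians crossed 0 for lung mitosis genes at 1 h (-0.15 to 0.048) and in skin for mitosis genes at 1 h (-0.47 to 0.0081), DNA replication genes at 1 h (-0.13 to 0.35), endothelium genes at 12 h (-0.079 to 0.39), adipocyte genes at 12 h (-0.17 to 0.50) and skeletal muscle genes at 12 h (-1.54 to 0.15) and 72 h (-1.15 to 0.0063). The cause was not tested.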

Other observations

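For the clock genes, the test of a response in both tissues at 1 h was chosen only after the result was seen, as were the tests of the mean of both tissues, the splits of that mean with 1 array of each strain per group and the shuffles of strains within each time.

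Several genes differed between the strains over all times. Hc, the gene of complement component C5, whose loss in A/J is a known strain variant, had mean log2 ratios in lung of 0.08 ± 0.19 in A/J, 1.79 ± 0.31 in C57BL/6J and 1.22 ± 0.14 in C3H/HeMs (SD, n = 4 arrays, limma adjusted p = 0.00299). Alad, an enzyme of heme synthesis, was at -0.54, -2.10 and -0.48 in lung (limma adjusted p = 0.0024) and at 0.32, -1.12 and 0.87 in skin (adjusted p = 0.0378). Xdh, which makes uric acid, was at 1.93, 1.25 and 0.45 in lung and 1.42, 1.52 and -0.30 in skin. These 3 genes were picked after their values were seen.

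Genes that rose together in lung at 12 h were at different points 1 h after irradiation. At 1 h Cdkn1a was already at 2.23 and Ccng1 at 0.69, whereas Exoc4, which is in none of the p53 target genes listed, was at 0.02 ± 0.15 SE. The difference between 1 h and 72 h passed for Exoc4 and Ephx1 and did not pass for Cdkn1a. No feature passed it with the set of the lung arrays as a block, with only the groups compared or without A/J or C3H/HeMs. Whether the courses of these genes differ from each other was not tested.

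At 1 h the clock output genes Nr1d2, Per3 and Hlf were below the control in every strain in lung and skin, and the core genes Arntl and Clock were above it except Arntl in C3H/HeMs skin, at -0.17. The mean change of Nr1d2, Per3 and Hlf minus that of Arntl and Clock was below 0 in 6 of 6 strain and tissue pairs at 1 h, with a median of -1.29, in 3 of 6 at 12 h and in 6 of 6 at 72 h, with a median of -0.60. At 12 h, sampling at another time of day than the controls was predicted to give mostly 1 sign, and the pairs lay 3 of 6 on each side. This argues against 1 shift of the hour that moved these genes alike in every strain and tissue. It cannot decide on hours that differed between strains or tissues, or on an hour at which these genes read as in the controls. At 1 h sampling at another time of day was left open, since Usp2, Wee1 and Per1 were below the control in 9 of 18 cases, but in 8 of 9 in lung and 1 of 9 in skin, so that the sum of the 2 tissues says little. A response of the clock to irradiation in both tissues at 1 h, with 6 of 6 pairs, may be the source but cannot be told apart from the hour of sampling or from other effects of handling, since no control sampled at the same hour was analysed here.

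The arrays were also split in other ways, to count how often a split gave as much as the real one. For each time against control and for 72 h against 1 h, 10 splits are too few for a share under 0.05. In lung, 3 of 10 splits at 1 h gave as many features as the real one (real 1, highest other 7), 1 of 10 at 12 h (10 and 0), 1 of 10 at 72 h (10 and 0) and 1 of 10 for 72 h against 1 h (2 and 0). In skin the real count was 0 by limma each time, so that 10 of 10 says nothing, at 1 h (highest other 0), 12 h (5), 72 h (0) and 72 h against 1 h (0). For lists, adjusted within each time, the shares were 3 of 10 (8 and 8), 7 of 10 (4 and 7) and 8 of 10 (3 and 9) in lung at 1 h, 12 h and 72 h and 4 of 10 (12 and 14), 1 of 10 (13 and 12) and 2 of 10 (11 and 11) in skin.

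The share of splits that called as many features as the real one was under 0.05 for the strain differences in lung (1 of 100 splits, real 258, highest other 69) and skin (4 of 100, real 33, highest other 71). It was also under 0.05 with strains shuffled only within each time (1 of 100 in each tissue, highest other 63 in lung and 17 in skin), and for the mean of both tissues at 12 h (2 of 100, 39 and 41) and 72 h (1 of 100, 17 and 2). The splits were not repeated with the set as a block. As the arrays that stand apart hold none of C57BL/6J, they cannot tell strain from set in lung. For the mean at 1 h chance was not excluded among the 100 splits (6 of 100, 2 and 139), which can put 2 arrays of a strain in 1 group. Among the 32 splits that kept 1 array of each strain and tissue in each group, none but the real one called as many for the mean at 1 h (1 of 32, 2 and 0), 12 h (1 of 32, 39 and 4) and 72 h (1 of 32, 17 and 0). A share of 1 of 32 is the smallest these splits can give, and at 1 h it rests on 2 features. For all irradiated arrays against controls in lung, as many were called in 2 of 64 splits that took 1 control from each strain (1 and 1). Among all splits this was so in 11 of 100 (1 and 950), so chance was not excluded by these splits. In skin the real count was 0 by limma, so that 64 of 64 (highest other 0) and 100 of 100 (highest other 231) say nothing. The same holds for the difference between skin and lung, with 100 of 100 at 1 h, 12 h and 72 h (real 0 by limma each time, highest other 139, 41 and 17). The splits with 950, 231 and 139 features called many more than the real ones, which points to a structure of the samples. As controls, the split with 950 took the A/J control and 1 h and C3H/HeMs control arrays. All 4 lung arrays that stand apart lay on the other side. That with 231 took the C3H/HeMs control and 1 h and C57BL/6J 1 h arrays. That with 139 for the mean took the same 3 skin arrays and the C57BL/6J control and 1 h and C3H/HeMs control lung arrays. What the arrays of these splits share was not tested.

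Some probes without a symbol carried the same value as many others on an array. In all, 69 such probes shared the commonest ratio of the array on at least 5 arrays, and 6 of the 23 skin features with 2-fold changes at 72 h were among them. Of the same 23 features 10 had no symbol. None of the features called in lung at 1 h, 12 h or 72 h had a ratio of exactly 0 on a lung array.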
